A study of Rattus norvegicus with 6 samples.

How the data were processed

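Whole back skin from vehicle-treated and afatinib-treated rats was profiled by RNA sequencing, with 3 libraries per group. Per the labels' protocols, the skin was frozen, RNA was extracted with Trizol, and 1 µg of total RNA went into each Illumina library. Per the labels, HISAT2 2.0.5 (a spliced aligner), featureCounts 1.5.0-p3 (a read counter) and DESeq2 1.16.1 (a differential expression test) are named in the submitters' processing notes, without their settings. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without these settings, reads shared by near-identical or overlapping genes cannot be told apart in the counts.

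The deposited values are raw read counts, 1 table per library, per the file headers and the values, which were whole numbers with a different total in each library. All 6 tables listed the same 33692 features, of which 32545 carried Ensembl rat gene identifiers and 1147 were loci with a serial number, for which the files give no gene. These unnamed loci held between 1.06% and 1.61% of the counts of a library and were kept in the tests. The tables hold no row of unassigned reads.

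The tables hold identifiers without gene symbols. The reference table used for names (47357 rat genes, assembly GRCr8) held an Ensembl identifier for 0 of its genes, and 0 of the 33692 features matched it by any identifier. No gene is therefore named here, no coordinates are given, and the 22 gene lists written before the data were examined (drug targets, pathways and cell type markers) were not tested. The rule for naming genes, also fixed before the data were examined, took the 8 largest changes in each direction among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, together with 3 members of each list and the ErbB receptors. It could name no gene. In its place, the 2 Ensembl identifiers with the smallest p in each direction are given, a choice made after the values were seen.

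Samples were grouped and numbered by the titles in the labels. The deposited column headings number the afatinib libraries 3, 4 and 5 where the titles number them 1, 2 and 3, so afatinib replicate 3 here is the library headed 5. The vehicle libraries carry the same numbers in both. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. Total counts per library ran from 15304166 to 18494281, so that 3 counts corresponded to between 0.162 and 0.196 CPM. Such floors cover counting error only. No pair of libraries was a repeated deposit of 1 library: the chi-square per degree of freedom was at least 28.2 over features with 10 or more counts in the pair. This value does not show that the libraries came from separate animals.

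From the deposited counts, features with low counts were removed with the default settings of filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 15497 features, 739 of them unnamed loci. Libraries were scaled by TMM, and afatinib was compared with vehicle by edgeR's robust quasi-likelihood test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method and compared with 0.05. CPM values printed below use the TMM-scaled library sizes. Correlations and principal components used log2 CPM with a prior count of 2. Library-level measures were compared by two-sided exact permutation tests, for which 3 against 3 libraries allow no p below 0.1.

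The alternatives were RLE and upper quartile scaling, no filter, a filter of 5 CPM in 3 samples, DESeq2 1.42.0, limma 3.58.1 with voom, the replicate number as a block, a test against a change of 1.5-fold, and each library left out in turn. Sample quality weights, a non-robust fit, removal of the unnamed loci, thinning of all libraries to the smallest total and the repeats of the DESeq2 count were added after seeing the data. DESeq2 applied its own filter, gave no adjusted p for 6620 of the 21840 features with a count, and was run on the full tables.

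The procedure was tested on simulated data. Counts for the 15497 tested features were drawn with the means, the dispersions estimated by edgeR and the library sizes of the real libraries. Of these features, 200 above a low abundance limit were changed. Each feature was drawn independently, so shifts of a library shared by many features were not simulated. At an adjusted p of 0.05, edgeR recovered 10 of 100 features changed by 2-fold and 73 of 100 changed by 4-fold, with 6 false calls among 89. DESeq2 recovered 28 and 89 of these features, with 56 false calls among 173. Limma voom recovered 9 and 60, with 5 false calls among 74.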

Results

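Afatinib is an irreversible inhibitor of the ErbB family of receptor tyrosine kinases, to which the epidermal growth factor receptor (EGFR) belongs. Skin rash is a common adverse effect of EGFR inhibitors. The series compared the transcriptome of rat back skin after afatinib with that of skin after vehicle, with 3 libraries in each group, to find early changes in the affected skin. The 3 vehicle libraries held 18494281, 17473766 and 17426909 counts, and the 3 afatinib libraries held 15304166, 16240325 and 16840331 counts. Every afatinib total was below every vehicle total (two-sided exact permutation test, p = 0.1, the smallest value that this design allows). Adjusted by the Benjamini-Hochberg method over 6 library measures, this permutation p was 0.48. Between 18570 and 19314 of the 33692 features had at least 1 count in a library, and 11852 features had none in any library.

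Counts were concentrated in few features, and the degree of this concentration varied between the afatinib libraries. The 10 most abundant features of each vehicle library held 17.7% ± 1.24 of its counts (SD, n = 3), against 15.0% ± 5.08 (SD, n = 3) in afatinib libraries. This difference was within the spread between libraries (two-sided exact permutation test, p = 0.4, Benjamini-Hochberg adjusted p = 0.48 over 6 library measures). The share was 10.6% in afatinib replicate 1, 13.8% in replicate 2 and 20.6% in replicate 3, while the vehicle libraries lay between 16.2% and 18.5%. The share held by the 100 most abundant features was 37.7% ± 2.42 in vehicle and 32.7% ± 7.76 in afatinib libraries (SD, n = 3 each), and the same order of the afatinib replicates was seen, with 26.5%, 30.1% and 41.4%.

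The libraries were compared with each other over the 15497 tested features. Pearson correlations of log2 CPM, taken across features, averaged 0.949 between vehicle libraries, 0.939 between afatinib libraries and 0.915 between libraries of different groups. Afatinib replicates 1 and 2 resembled each other (0.967). Afatinib replicate 3 correlated more closely with each vehicle library (0.960, 0.943 and 0.958 with replicates 1, 2 and 3) than with afatinib replicate 1 (0.907), and its correlation with afatinib replicate 2 was 0.944. On the first principal component, which carried 60.2% of the variance, afatinib replicates 1 and 2 had scores of 89.1 and 55.4, and the vehicle libraries had scores of -27.8, -86.6 and -12.5. Afatinib replicate 3 had a score of -17.7 and lay within the range of the vehicle libraries.

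**Figure D1:**
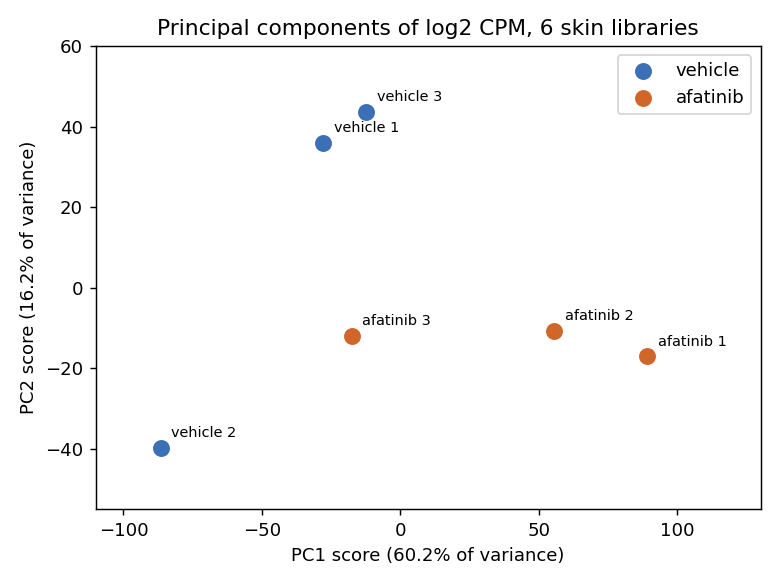
Principal component scores of the 6 libraries from log2 CPM of 15497 features, with the first component (60.2% of variance) on the horizontal axis and the second (16.2%) on the vertical axis, each point being 1 library. Afatinib replicates 1 and 2 lie apart at the right, and afatinib replicate 3 has a first score of -17.7, between those of vehicle replicates 1 and 3.

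The main comparison asked which transcripts differed between afatinib-treated and vehicle-treated skin. With all 6 libraries, 0 of 15497 features passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.185. At an unadjusted p under 0.05 there were 3023 features (19.5% of those tested), where an even spread of p-values gives 775. The 9 other ways to divide the libraries into 3 and 3 gave between 122 and 2640 such features. The count was 5315 without afatinib replicate 3, 1796 and 1725 without afatinib replicates 1 and 2, and 1793, 1982 and 2443 without vehicle replicates 1, 2 and 3. Of the 3023, 1598 were higher and 1425 lower in afatinib-treated skin. In 2003 features the lowest afatinib library lay above the highest vehicle library, and in 2050 the order was the opposite. Together these made up 26.2% of the tested features, against 10% by chance for 3 against 3 libraries. Features are not independent, so a single split can lie far from 10% without an effect of treatment. The share was not computed for the other splits. The fitted difference exceeded 2-fold in 1134 features with higher and 599 with lower values in afatinib-treated skin, none of which passed the adjusted test.

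**Figure D2:**
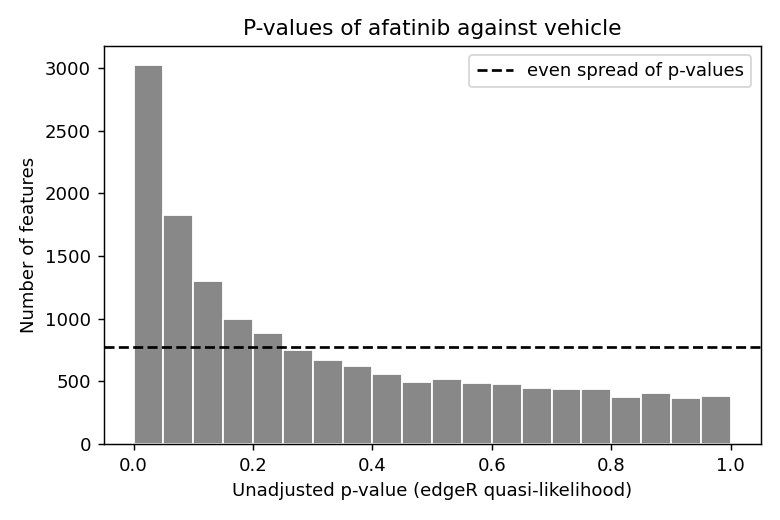
Number of features (vertical axis) per bin of the unadjusted p-value of edgeR's quasi-likelihood test (horizontal axis, bins of width 0.05) for afatinib against vehicle. The first bin holds 3023 features, and the dashed line marks the 775 per bin of an even spread.

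The number of features called depended on the test. Limma voom called 0 features (2899 at an unadjusted p under 0.05, smallest adjusted p 0.211). DESeq2 called 1032 features at an adjusted p under 0.05, of which 593 were higher and 439 lower in afatinib-treated skin, with a median size of change of 1.24 on the log2 scale. It placed 3616 features at an unadjusted p under 0.05. Of the 1032, 952 had also been tested in edgeR, and all 952 had an unadjusted p under 0.05 there, on the same counts. In 873 of them the libraries of the 2 groups did not overlap. Both counts are favoured by the selection, since the features were called on these same libraries, and are no separate support for the calls. The spread between libraries of one group corresponded to a biological coefficient of variation of 33.1% in edgeR. On data simulated with these dispersions, independently for each feature, edgeR recovered 10 of 100 changes of 2-fold and 73 of 100 changes of 4-fold. Recovery in the real libraries may differ, since shifts shared by many features were not simulated.

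The number of features that passed also depended on which libraries were included, in DESeq2 as well as in edgeR. Without afatinib replicate 3, edgeR's quasi-likelihood test called 1627 of 16014 features, 829 higher and 798 lower after afatinib, and DESeq2 called 4085. Leaving out vehicle replicate 2 gave 51 calls in edgeR, all of lower features, leaving out vehicle replicate 1 gave 1, and leaving out any of the other 3 libraries gave 0. In DESeq2, the number of calls fell to 399, 490 and 744 without vehicle replicates 1, 2 and 3, and to 336 and 270 without afatinib replicates 1 and 2.

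**Figure D3:**
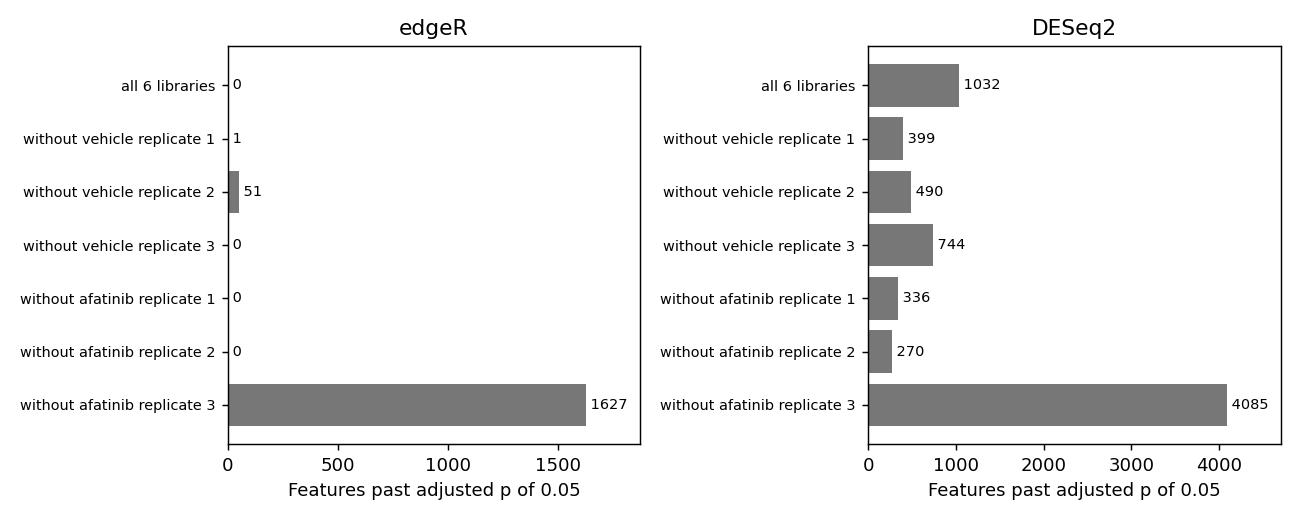
Number of features past an adjusted p of 0.05 (horizontal axes, starting at 0) with all 6 libraries and with each library left out in turn, for edgeR on the left and DESeq2 on the right. Both counts were highest without afatinib replicate 3, at 1627 and 4085.

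The 2 Ensembl identifiers with the smallest p in each direction were examined library by library, a choice made after the values were seen. The deposited tables do not pair identifiers with gene names. ENSRNOG00000058186 had 60.4 ± 3.60 CPM in vehicle and 124.9 ± 5.23 CPM in afatinib libraries (SD, n = 3 each), a log2 fold change of 1.05. ENSRNOG00000007387 had 22.8 ± 1.63 CPM in vehicle and 89.5 ± 29.3 CPM in afatinib libraries (SD, n = 3 each), a log2 fold change of 1.98. ENSRNOG00000045797 had 61.4 ± 12.3 CPM in vehicle and 18.4 ± 1.01 CPM in afatinib libraries (SD, n = 3 each), a log2 fold change of -1.74. ENSRNOG00000043114 had 48.7 ± 6.22 CPM in vehicle and 16.8 ± 2.28 CPM in afatinib libraries (SD, n = 3 each), a log2 fold change of -1.54. These log2 fold changes are those of edgeR. Limma voom's own estimates for the 4 features were 1.05, 1.93, -1.72 and -1.54, with standard errors of 0.11, 0.25, 0.18 and 0.16, in the same order. Each had an adjusted p of 0.185 in edgeR's quasi-likelihood test, and adjusted p-values of 2.42e-11, 1.42e-08, 5.24e-11 and 1.24e-09 in DESeq2. Without afatinib replicate 3 the 4 features passed in edgeR, with adjusted p-values between 0.0186 and 0.0234. None of the 4 passed in edgeR when any of the other 5 libraries was left out, with adjusted p-values between 0.0557 and 0.457. Chosen for their small p over all 6 libraries, they do not represent the other features.

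**Figure D4:**
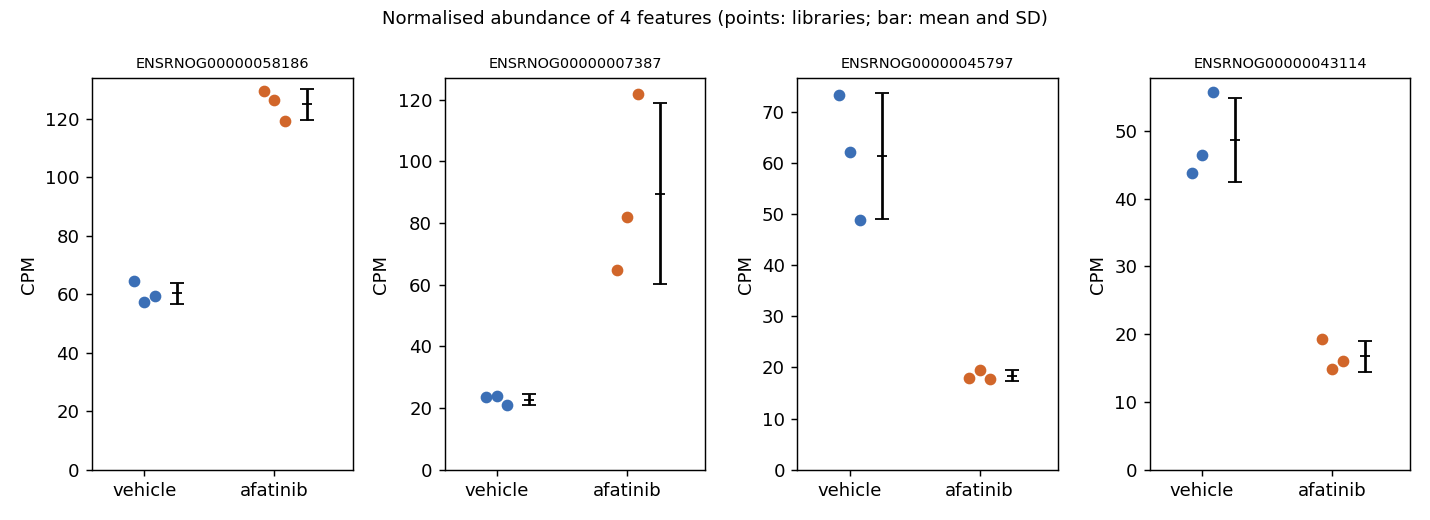
CPM (vertical axes, starting at 0) of the 4 best-ranked Ensembl identifiers in vehicle and afatinib libraries; points are single libraries, and the black mark is the mean with its SD (n = 3 per group). The 3 afatinib libraries lie above all vehicle libraries for the first pair and below them for the second pair, which the choice by smallest p favours.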

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

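The choice of test and the libraries included changed the counts of calls. In edgeR, RLE or upper quartile scaling, no filter, the 5 CPM filter, the 1.5-fold test, a non-robust fit, removal of the unnamed loci and thinning to the smallest total all gave 0 calls, as did limma voom. DESeq2 gave 1032 (593 higher, 439 lower), and limma voom with sample quality weights, added after seeing the data, gave 5246 (2446 higher, 2800 lower), with weights of 2.50, 0.63 and 0.85 for vehicle replicates 1, 2 and 3 and 0.50, 5.46 and 0.28 for afatinib replicates 1, 2 and 3, so that 1 library per group carried most of the weight. Leaving out 1 library at a time moved edgeR's counts between 0 and 1627 (higher, 0 to 829; lower, 0 to 798), the upper ends being without afatinib replicate 3. It moved the DESeq2 counts between 270 and 4085 (higher, 127 to 2102; lower, 143 to 1983), again highest without that library. The DESeq2 count was 970 on thinned libraries, 1013 without the features at 0 in all libraries and 1026 without the unnamed loci. The 4 identifiers given kept their direction under each edgeR and limma setting and in DESeq2 with all 6 libraries. Their choice by smallest p on these same libraries made a change of direction unlikely, so this is no separate support. The replicate numbers of the titles gave no sign of a pairing: deviations from the group means correlated by 0.20, -0.21 and -0.39 for numbers 1, 2 and 3, and not every library correlated best with its own number. By the column headings the groups share only the number 3, held by vehicle replicate 3 and afatinib replicate 1, whose deviations correlated by 0.32. The highest value, 0.43, was between vehicle replicate 2 and afatinib replicate 3. Deviations within a group sum to 0, so these values cannot exclude a pairing. With the replicate block, edgeR gave 0 calls and DESeq2 gave 372 (229 higher, 143 lower). Calls lost under this block are not a measure of weaker effects. The gene list tests were not run, because no feature could be paired with a symbol. At this number of libraries, with each feature simulated independently, edgeR recovered 10 of 100 changes of 2-fold and 73 of 100 of 4-fold. The simulation held no shift shared by many features, such as that of afatinib replicate 3, so recovery in the real libraries may differ.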

Other observations

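Of the tests below, those on depth and abundant features for afatinib replicate 3 and on the splits under quality weights were set down before their results were seen, and the others after.

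Afatinib replicate 3 lay near the vehicle libraries. On the line between the group means computed without the library in question, where 0 is the vehicle mean and 1 the afatinib mean, it lay at 0.27, against 1.32 and 1.03 for afatinib replicates 1 and 2 and 0.27, -0.03 and 0.44 for vehicle replicates 1, 2 and 3. Each library thus has its own line. For every library but afatinib replicate 3, the afatinib mean includes that replicate, so positions of different libraries are not strictly comparable. These positions do not exclude a swap with a vehicle library. No vehicle library lay beyond 0.439, but afatinib replicate 3 itself lay at 0.27, so a library of that group need not lie near 1. The position of afatinib replicate 3 was 0.271 with all libraries thinned to the smallest total and 0.275 without the 100 most abundant features. Neither step moved any library by more than 0.0065. A rise to 0.8 or more was predicted if depth or these features had placed it there, and it stayed under 0.5. Its position was thus nearly the same with equal totals and without these 100 features. Because both steps moved every library so little, they cannot show what depth or abundant features contributed to it. A single wrong label or missed exposure stays open: of the 4 ways to put 1 of the other libraries with afatinib replicates 1 and 2, only 1, the real one, gave as many DESeq2 calls (1032, highest other 592 with vehicle replicate 3), and 4 ways cannot give a share under 0.05. Against it, over the 1000 features that best separated afatinib replicates 1 and 2 from a pair of vehicle libraries, afatinib replicate 3 lay on the afatinib side in 86.5%, 77.2% and 88.0%, and the vehicle library held out each time (replicates 1, 2 and 3) in 68.7%, 39.9% and 81.3%. The size was small: afatinib replicate 3 showed a median of 0.30, 0.22 and 0.33 of the difference. The held-out vehicle libraries showed 0.12, -0.09 and 0.24. Afatinib replicate 3 was the higher in each of these 3 matched comparisons, which share libraries and are too few for a test; differences between animals or in the skin taken were not tested.

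The tests disagreed, with 0 calls in edgeR and 1032 in DESeq2. Without afatinib replicate 3, 1627 features passed in edgeR, and at most 51 without any other single library. Leaving it out lowered the common dispersion from 0.109 to 0.0945 and raised the median size of change from 0.32 to 0.42 on the log2 scale, so the spread it adds cannot be told apart from the smaller difference it brings. DESeq2 made 970 calls once all libraries were thinned to the smallest total, against 1032 before. Most calls thus remained with the totals made equal. The step moved the count too little to decide whether a difference in depth between the groups contributed to the calls. On simulated data DESeq2 made 56 false calls among 173, and edgeR 6 among 89, so part of the 1032 may be false. That simulation took edgeR's dispersions as true and changed 200 of 15497 features. Its share of false calls therefore cannot be carried over to the 1032, and it does not rank the tests.

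The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. In edgeR the real split gave 0 calls and the highest other 1; a count of 0 is met by all 10 splits whatever the data, so it says nothing. At an unadjusted p under 0.05 the real split gave 3023 features and the highest other 2640 (1 of 10 as large), while leaving out 1 library moved the real count between 1725 (without afatinib replicate 2) and 5315 (without afatinib replicate 3). In DESeq2 the real split gave 1032 and the highest other 592 (1 of 10 as large). With quality weights the real split gave 5246 and the highest other 2980 (1 of 10 as large). For the last 3 counts, the highest other split exchanged vehicle replicate 3 with afatinib replicate 3.

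Some differences between libraries of one group correlated with differences in the other group. Across features, the difference between vehicle replicates 3 and 2 correlated with that between afatinib replicates 3 and 1 by -0.42, and the 9 such correlations between a vehicle pair and an afatinib pair, which share no library, had sizes from 0.04 to 0.42. Features are not independent replicates, and no test was run on these values.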
